A study of Homo sapiens with 5 samples.

How the data were processed

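Messenger RNA levels were measured on 5 Affymetrix arrays, each hybridised with RNA from the human prostate cancer cell line PC-3. The arrays held 1 culture grown flat (2D), 1 spheroid culture, 1 line with a control hairpin against GFP (shGFP) and 2 lines with different hairpins against TRIB1 (shTRIB1-1 and shTRIB1-2). Groups were taken from the sample labels. Per the labels' protocols, total RNA was isolated with RNeasy columns and biotin-labelled cRNA was made by the standard Affymetrix procedure. The labels give 1 growth protocol, in dishes, for all 5 samples, the spheroid sample included. How the spheroids were grown is not given in the sources used here.

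The deposited values are probe set intensities on a linear scale, which the authors made with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes. That the values are linear was read from the values. The version of RMA, the chip definition file and the step that turned its log2 output back to linear values are not given in the sources used here. Quantile normalization gives every array nearly the same distribution, so a change that moved most genes one way would be hidden. The median intensity was 32.98 on the shGFP array, 32.97 and 33.26 on the shTRIB1-1 and shTRIB1-2 arrays, 32.98 on the 2D array and 33.36 on the spheroid array. Between 36.06% and 36.60% of probe sets per array were at or above an intensity of 64. Between 10.5% and 12.8% of genes had the same value on both arrays of a pair, and differences of exactly 0 therefore occur. Arrays have no sequencing depth, and the number of arrays limits the precision.

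Log2 was taken of each intensity, with no pseudocount, and is called the level. Of 54675 probe sets, 62 were Affymetrix controls, 41097 carried 1 gene symbol, 1801 carried several and 11777 carried none, the controls included. Names came from the platform annotation. The Entrez identifiers of 41043 probe sets matched the RefSeq gene table of GRCh38.p14, which updated 0 symbols and was used for names alone. Probe sets with several symbols or none entered no comparison of genes. Each of 19775 genes was represented by its probe set with the highest mean level over the 5 arrays. A gene entered a comparison if its level was at least 6 on any compared array. The size of a difference in which the other array lies below 6 rests on a signal near background.

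The spheroid array was set against the 2D array as a log2 difference per gene, without a test, because each condition had 1 array. The arrays labelled shTRIB1-1 and shTRIB1-2 were set against the shGFP array by the difference per hairpin, its mean and SD, and by limma with an intensity trend and Benjamini-Hochberg adjustment at 0.05. That fit leaves 1 residual degree of freedom, taken from the difference between the 2 hairpins. The SD comes from the same difference, so it does not hold the spread of the shared shGFP array. A gene was counted as different at a log2 difference of 1 (2-fold), on both hairpin arrays where hairpins were counted. For the correlation and shared genes of the 2 hairpins, 100 simulations drew unchanged arrays against 1 shared control, with noise from the difference between the hairpin arrays. The correlation of spheroid and hairpin differences was not simulated, and their overlap was set against independent lists only.

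Before the data were examined, 23 gene lists were fixed, holding 411 genes, of which 362 had a probe set. For each list and comparison the median difference was ranked among 10000 random lists of the same size and matched level (20 level bins), as a percentile that describes these arrays. For the hairpins, limma's camera tested each list against all other genes with a preset correlation of 0.01 between genes. That version treats genes as the units, so its p-value does not measure the spread between arrays. Camera was run again with the correlation estimated from the data. That run has 1 residual degree of freedom, as in the limma fit, so it could hardly call any list. Its estimate rests only on which hairpin array is higher for each gene. Limma was also adjusted over each list alone. The lists cover ER chaperones and folding enzymes, ER-associated degradation and sensors of the unfolded protein response, ATF4 and integrated stress response genes, heat shock proteins, the hypoxia response, G2 and M phase, DNA replication, cholesterol biosynthesis, inflammatory cytokines and NF-kB targets, and interferon-stimulated genes. The others are epithelial junctions, mesenchymal genes, extracellular matrix and integrins, stem and tumour-propagating cell markers, TRIB1 family and partners, prostate luminal and androgen receptor genes, neuroendocrine genes, blood and endothelial markers, antigen presentation, oxidative phosphorylation, ribosomal proteins, autophagy and lysosome, and apoptosis regulators.

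The rule for named genes was also fixed then. It took TRIB1, the 12 highest and 12 lowest differences between spheroid and 2D, and the 12 highest and 12 lowest genes for the hairpins, ranked by the smaller absolute difference of the 2 hairpins with 1 sign. It further took 5 genes for each pair of directions of both comparisons and the 4 members of each list with the largest absolute difference in each comparison. HSPA5, HSP90B1, PDIA4, CALR, DDIT3, CD44, MKI67 and VEGFA were named in advance.

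The steps were tested on simulated data for the comparison of the hairpins with shGFP, over 10522 genes with 200 changed and 10 runs. With noise drawn from the differences between these arrays, limma recovered 0% of genes changed by 1.5 and 0% of those changed by 3 on the log2 scale, and called 0 unchanged genes. The 2-fold rule on both hairpins recovered 82.2% and 99.9% and called 166.9 unchanged genes per run. With a constant SD of 0.1, limma recovered 100% at both sizes and called 9.5 unchanged genes per run. Camera with the preset correlation called the ER chaperone list in 20 of 20 runs after it was lowered by 0.5, and called 1 list over the 20 runs without a change. That noise was independent between genes, so these runs say nothing of genes that vary together. In shuffled values, the ER chaperone list ranked at percentile 38.4, and at percentile 0 once it was lowered by 0.5.

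The alternatives were median centring, cyclic loess, no level filter, a level filter of 8, the median over a gene's probe sets, leaving out probe sets that can match several transcripts (_x_at or _s_at), the mean of 2D and shGFP as the reference, each hairpin alone, a fit over all 5 arrays, a fit with shGFP and 2D as controls and limma without a trend. A further 3 were added after seeing the data. These were the lists and the 2-fold counts with the 2D array alone as the reference, and the correlation without the cell cycle lists. R 4.3.3 and limma 3.58.1 were used.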

Results

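Gene expression was measured on 5 arrays of PC-3, an androgen-independent human prostate cancer cell line that came from a bone metastasis. Per the labels, 1 array held PC-3 cells from a flat (2D) culture and 1 held cells from spheroids, which are clusters grown in 3 dimensions. A further 3 arrays held PC-3 cells with short hairpin RNAs, 1 with a control hairpin against GFP (shGFP) and 2 with different hairpins against TRIB1. TRIB1 is a pseudokinase that brings proteins such as C/EBP alpha to the ubiquitin ligase COP1. The study asked which genes differ between 2D and spheroid growth and which depend on TRIB1. The 2D, spheroid and shGFP conditions have no replicate, so differences between them have no replicate check. Nothing in the labels says whether arrays came from separate cultures. A p-value per gene here measures the spread between these arrays alone, which may be technical. A camera p-value with the preset correlation compares a list with all other genes instead. A shift of the list in the lone shGFP array would therefore give a low value too.

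The signal of the TRIB1 probe set was high on every array and was not clearly lower with the hairpins against TRIB1. Its level, the log2 of the RMA intensity, was 11.97 on the shGFP array, 11.91 on the array labelled shTRIB1-1 and 11.76 on the array labelled shTRIB1-2. The differences from shGFP were -0.055 and -0.20, a mean of -0.13 ± 0.10 (SD, n = 2). That is 1.09-fold, and limma did not call it. TRIB1 was at 11.04 on the 2D array and 11.23 on the spheroid array, a difference of 0.19. Against the mean of the shGFP and 2D arrays the signs turned, to 0.33 for the mean of the hairpins and -0.28 for the spheroid array. This probe set lies at percentile 98.4 of all probe sets by mean level, and the other 2 TRIB1 probe sets were near 3.5 on every array and carry little information. The arrays therefore give no sign of depletion at the level of this messenger RNA, and which part of the transcript the hairpins or the probes cover is not given in the sources used here. For this reason the hairpin arrays are called below by their labels, and every direction given for them is that of the labelled array.

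**Figure D1:**
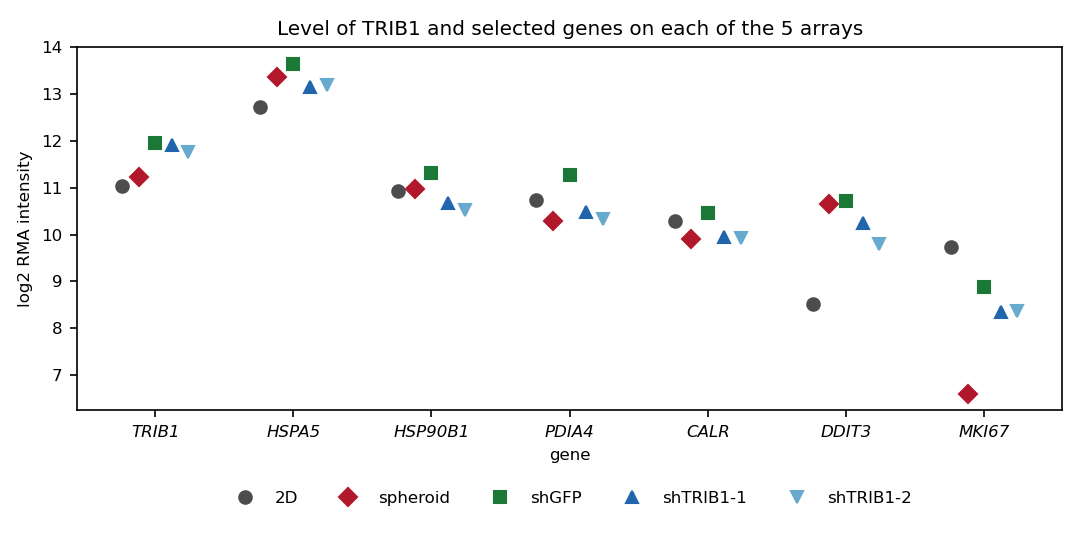
Level (log2 RMA intensity, vertical axis) of TRIB1 and 6 genes fixed in advance (horizontal axis), with 1 point per array for the 2D, spheroid, shGFP, shTRIB1-1 and shTRIB1-2 arrays. TRIB1 lay at 11.97 with shGFP and at 11.91 and 11.76 with the hairpins against it, while HSPA5 lay at 13.65 with shGFP, 13.15 and 13.18 with those hairpins and 12.71 in 2D.

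Internal control probe sets separated the arrays into those with hairpins and those without. The ratio of 5′ to 3′ signal of actin was 0.436 on the shGFP array and 0.445 and 0.442 on the arrays labelled shTRIB1-1 and shTRIB1-2. It was 0.184 on the 2D array and 0.131 on the spheroid array. The thr spike, a bacterial RNA added to each sample, gave 0.264, 0.269 and 0.217 on the 3 hairpin arrays, 0.113 on the 2D array and 0.0913 on the spheroid array. The dap, lys and phe spikes split the arrays in the same way. For GAPDH the 2D array (0.895) lay near the hairpin arrays (0.929 to 0.944), and the spheroid array alone stood apart (0.763). Spikes do not come from the cells, so their ratios argue against damage to the cells' RNA as the whole cause. The part of each step (RNA, labelling, hybridisation or scanning) was not tested. Each main comparison lies within 1 of these sets of arrays, whereas a comparison across them includes this difference.

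Spheroid cells were compared with 2D cells to find genes that depend on growth in 3 dimensions. Genes of cell division were far lower in the spheroid array, whereas the lists of ER-associated degradation and unfolded protein sensors, integrated stress response, inflammation, interferon-stimulated genes and lysosomes had higher medians. Of 10570 genes at a level of at least 6, 534 were at least 2-fold higher in the spheroid array and 553 were at least 2-fold lower. At a level filter of 8, 330 were higher. The largest positive difference was that of DHRS9, a retinol dehydrogenase, at 5.58 (47.8-fold). FABP4, a fatty acid carrier, differed by 5.27, the phospholipase PLA2G4A by 5.23 and the water and glycerol channel AQP3 by 4.99. RGS4, a regulator of G protein signalling, followed with 4.67. LRRC31 differed by 4.40 and S100A8, a subunit of calprotectin, by 4.26. The 5 others among the 12 highest lay between 4.07 and 4.15 and were LOC105375172, CYP4X1, FCGBP, the fibrinogen chain gene FGG and LINC02806. Apart from DHRS9, FABP4 and FCGBP, these genes were below a level of 6 in 2D, so their differences depend on a signal near background. S100A8 differed by 0.31 when probe sets ending in _s_at or _x_at were left out, and AQP3 by 1.28 as the median of its probe sets.

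The largest negative difference between spheroid and 2D was that of ANO1, a calcium-activated chloride channel, at -5.22 (37.2-fold). CALB1, a calcium-binding protein, differed by -3.80, the serpin SERPINB7 by -3.74 and the actin-binding calponin CNN3 by -3.63. The other 8 of the 12 lowest act in or around mitosis. The mitotic kinesin KIF20A differed by -4.13, the spindle protein ASPM by -3.97, the kinetochore protein SPC25 by -3.59, the kinesin KIF14 by -3.52, the kinetochore motor CENPE by -3.48 and the kinetochore scaffold KNL1 by -3.46. FAM83D and DEPDC1 differed by -3.42 and -3.39. ANO1 differed by -2.90 as the median of its probe sets. Of these 12 genes, all but SERPINB7, KIF14, FAM83D and DEPDC1 were below a level of 6 in the spheroid array (ANO1 at 3.14), so their exact differences and ranks rest on a signal near background.

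In the list of G2 and M phase genes, 20 of 20 measured members were at least 2-fold lower in the spheroid array, with a median difference of -2.78 (SD over members 0.627). CENPF differed by -3.37, the cyclin CCNB2 by -3.28 and the proliferation marker MKI67 by -3.14. Of 20 DNA replication genes, 17 were at least 2-fold lower and the median was -1.60. Examples are UHRF1, which maintains DNA methylation, at -2.37, the thymidylate synthase TYMS at -2.32, GINS2 at -2.23 and CDC45 at -2.22. Both list medians were below those of all 10000 random lists of matched level. The actin 5′ to 3′ ratio was also lower in the spheroid array, at 0.131 against 0.184.

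Stress response genes of the endoplasmic reticulum (ER) did not all move alike in the spheroid array. Of 13 genes of ER-associated degradation and unfolded protein sensors, 12 were higher and 4 were at least 2-fold higher, with a median of 0.81. The sensor kinase ERN1 differed by 1.79, its target transcription factor XBP1 by 1.17, the degradation factor HERPUD1 by 1.11 and the sensor ATF6 by 1.02. Of 21 genes of the integrated stress response, which ATF4 drives, 17 were higher and 4 were at least 2-fold higher, with a median of 0.70. The transcription factor DDIT3 (CHOP) differed by 2.14, ATF3 by 1.97, DDIT4 by 1.17 and NUPR1 by 1.08. With the mean of the 2D and shGFP arrays as the reference, these medians were 0.38 and 0.17. The 22 ER chaperones and folding enzymes were higher in 11 and lower in 11 cases, with a median of 0.02. Among them DNAJB9 was higher by 1.33, DNAJC3 by 0.87 and the main ER chaperone HSPA5 (BiP) by 0.66, while PDIA6 differed by -0.59, PDIA4 by -0.44 and CALR by -0.39. HSP90B1 differed by 0.05. The chaperone median was -0.25 against the mean of the 2D and shGFP arrays. The 10 heat shock proteins, among them the mitochondrial HSPD1 and HSPE1, had a median of -0.25, and the co-chaperone BAG3 differed by -0.59.

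Inflammatory and interferon genes were higher in the spheroid array. Of 10 inflammatory genes above the level filter, 7 were at least 2-fold higher and the median was 1.20. IL1B differed by 3.28, CXCL2 by 2.35, CCL20 by 2.22 and IL6 by 1.38. In 2D, CXCL2 (4.86), CCL20 (3.96), IL6 (5.16), CXCL3 (5.62) and TNFAIP3 (5.71) were below a level of 6, so the sizes of their differences rest on a signal near background. The median was 0.30 with no level filter and 0.33 against the mean of the 2D and shGFP arrays. Of 15 interferon-stimulated genes, 13 were higher and 6 were at least 2-fold higher, with a median of 0.73. IFI44L differed by 2.34, the antiviral synthetase OAS1 by 2.16, IFI6 by 2.03 and the transcription factor IRF9 by 2.00. The 10 antigen presentation genes had a median of 0.33, at percentile 96.7 of random lists, led by HLA-B at 1.30 and HLA-C at 1.23.

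Of 15 autophagy and lysosome genes, 13 were higher in the spheroid array and 3 were at least 2-fold higher, with a median of 0.58. The autophagy receptor SQSTM1 differed by 1.60, GABARAPL1 by 1.44 and WIPI1 by 1.04. Among 10 genes of the TRIB1 family and its partners the median was 0.66, with the phosphatase DUSP6 at 1.35, CEBPD at 1.20 and CEBPB at 0.94. This list shares CEBPB and TRIB3 with that of the integrated stress response. Of 12 cholesterol biosynthesis genes, 11 were lower and 3 were at least 2-fold lower, with a median of -0.69. The farnesyl diphosphate synthase FDPS differed by -1.19, IDI1 by -1.03 and NSDHL by -0.88. Against the mean of the 2D and shGFP arrays the medians were 0.28 for autophagy and lysosome genes, 0.34 for the TRIB1 family and -0.17 for cholesterol biosynthesis. The TRIB1 family median was 0.26 with no level filter. Among random lists of matched level, the medians lay at percentile 99.99 for autophagy and lysosome genes, 100 for the TRIB1 family and 0.02 for cholesterol biosynthesis.

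The remaining lists were mixed in the spheroid array. Hypoxia response genes had a median of 0.30 over 20 members, 11 higher and 9 lower, with ANGPTL4 at 2.72, NDRG1 at 1.55, ADM at 1.19, VEGFA at 0.98 and PDK1 at -1.01. The hypoxia median turned to -0.13 as the median over all probe sets of each gene and to -0.14 without _s_at and _x_at probe sets. The 14 epithelial junction genes had a median of -0.47, with CLDN1 at -1.72 and KRT7 at -1.08 but the tight junction protein OCLN at 2.17. That median turned to 0.0082 without _s_at and _x_at probe sets. The 11 mesenchymal genes had a median of -0.22, 3 of them 2-fold higher and 3 2-fold lower, with SPARC at 2.65 and N-cadherin (CDH2) at -2.19. The median turned to 0.18 without _s_at and _x_at probe sets. The 19 matrix and integrin genes had a median of 0.00, with LAMB3 at 1.35 and TNC at -2.01. The 9 stem cell markers had a median of -0.20, with KLF4 at 2.72, SOX9 at -0.88, ALDH1A3 at -1.70 and CD44 at -0.23. Oxidative phosphorylation (median -0.069, 17 genes), ribosomal proteins (0.0086, 15 genes) and apoptosis regulators (0.098, 14 genes) stood near 0. Of the prostate luminal genes 5 passed the level filter, with a median of -0.046, FKBP5 at -1.24 and STEAP2 at 1.12. ENO2, the 1 neuroendocrine gene above the filter, was at 0.77. Among blood and endothelial markers PECAM1 was at 1.96 and the hemoglobin gene HBB at 0.00.

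**Figure D2:**
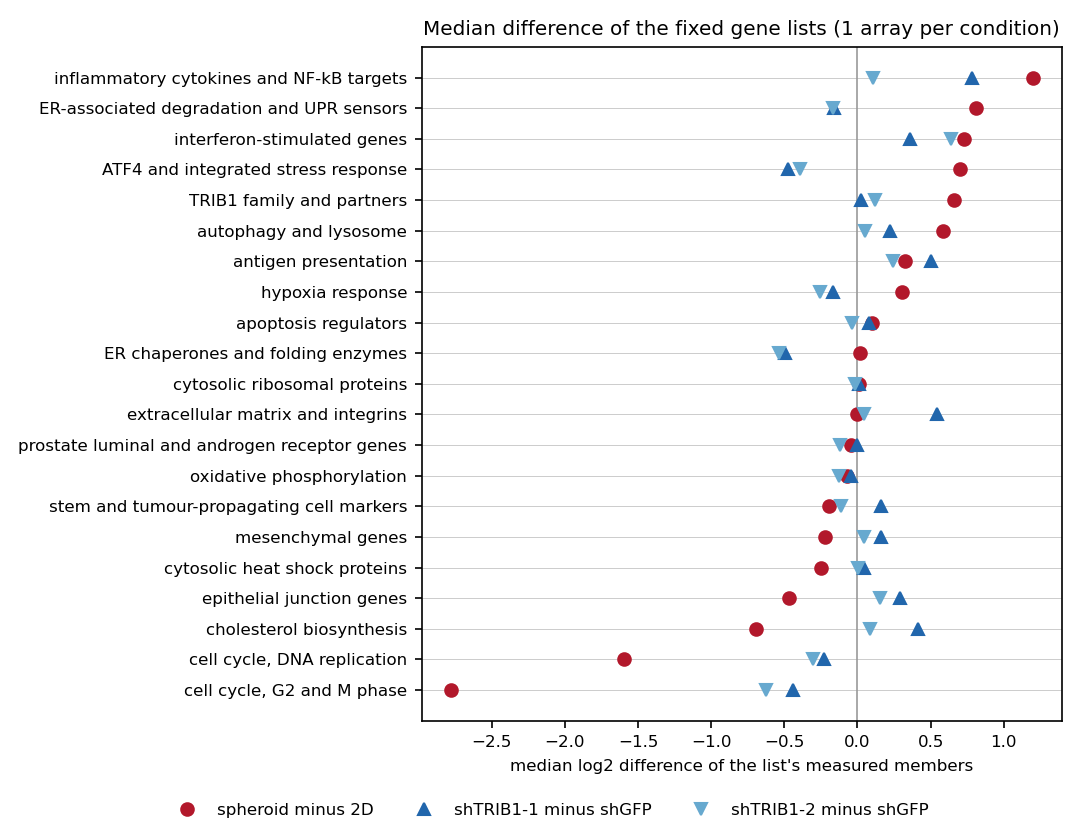
Median log2 difference over the measured members of each gene list (horizontal axis) for the lists with at least 3 measured members in both comparisons (vertical axis), with circles for spheroid minus 2D and triangles for the arrays labelled shTRIB1-1 and shTRIB1-2 minus shGFP. G2 and M phase genes lay at -2.78 in the spheroid array, and ER chaperones lay at -0.50 and -0.54 on the hairpin arrays and at 0.02 in the spheroid array.

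The arrays labelled shTRIB1-1 and shTRIB1-2 were compared with the shGFP array to find genes that depend on TRIB1. ER chaperones, integrated stress response genes and cell cycle genes were lower on both labelled arrays, and interferon and antigen presentation genes were higher. Of 10522 genes, 38 were at least 2-fold higher on both arrays and 9 were at least 2-fold lower. The array labelled shTRIB1-1 alone had 210 genes higher and 196 lower, the array labelled shTRIB1-2 alone 141 higher and 86 lower, and 18 genes differed 2-fold in opposite directions. On both arrays, 20 were higher and 4 lower with the median over a gene's probe sets, 23 were higher at a level filter of 8, and 82 were higher and 32 lower against the mean of shGFP and 2D. ADAMTS1, a secreted metalloprotease, was highest with 3.16 ± 0.48 (SD, n = 2), followed by the interferon-induced GTPase GBP1 with 2.99 ± 0.87. The others among the 12 highest were RGS4 (1.99 ± 0.75), the histone deacetylase HDAC9 (1.90 ± 0.61), GPCPD1 (1.77 ± 0.35), TNFAIP3 (1.70 ± 0.54), SLC16A14 (1.55 ± 0.24), DIPK1A (1.52 ± 0.29), HEG1 (1.49 ± 0.02), ZNF91 (1.45 ± 0.16), the collagen COL1A1 (1.41 ± 0.08) and FSTL1 (1.34 ± 0.03). TNFAIP3 restrains NF-kB signalling. Each SD is between the 2 hairpin arrays alone and is not the precision of a difference from the 1 shGFP array. The ranking by the smaller difference also favours genes on which the hairpins were alike. On the shGFP array ADAMTS1 (4.39), GBP1 (5.08), SLC16A14 (4.96), HDAC9 (5.88) and RGS4 (5.99) were below a level of 6, so their exact differences and ranks rest on a signal near background. As the median over all probe sets of a gene, HDAC9 differed by 0.0084, COL1A1 by 0.057, ZNF91 by 0.032, FSTL1 by 0, GPCPD1 by 0.92 and HEG1 by 0.99. DIPK1A differed by 0.025 without _s_at and _x_at probe sets. Against 2D alone GBP1 differed by 1.01, DIPK1A by 0.81, ZNF91 by 0.93 and SLC16A14 by -0.048.

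The lowest gene on both labelled arrays was CALB1, at -1.65 with each hairpin. It was followed by ATP8A2 (-1.58 ± 0.30), SLITRK6 (-1.44 ± 0.08), SHISA2 (-1.43 ± 0.08), PRKAR2A (-1.41 ± 0.40), the endotoxin receptor TLR4 (-1.30 ± 0.44), CHAC1 (-1.19 ± 0.19) and TSNARE1 (-1.16 ± 0.08). The vitamin D receptor VDR (-1.15 ± 0.18), ZNF232-AS1 (-1.11 ± 0.20), LRRC34 (-1.09 ± 0.06) and RGS7 (-1.03 ± 0.10) completed the 12. ATP8A2, TLR4 and LRRC34 were below a level of 6 on both labelled arrays, so their exact differences and ranks rest on a signal near background. As the median over all probe sets, TSNARE1 differed by -0.022, RGS7 by -0.054, TLR4 by -0.35, VDR by -0.60 and PRKAR2A by -0.68. Without _s_at and _x_at probe sets, TLR4 differed by -0.21, ZNF232-AS1 by -0.47, LRRC34 by -0.70 and ATP8A2 by -0.99. Against the 2D array, CALB1 was higher on the labelled arrays by 1.67 and CHAC1 by 0.21, while ATP8A2 differed by -0.21, SLITRK6 by -0.52, TLR4 by -0.60, TSNARE1 by -0.64 and LRRC34 by -2.14. Limma called 0 genes, with a smallest adjusted p of 0.951 (0.557 to 0.998 over the alternatives). At an unadjusted p under 0.05 it held 356 genes, 3.38% of those tested, 191 higher and 165 lower. In simulated data of this design, with noise drawn from the differences between these arrays, limma recovered no gene changed by 3 on the log2 scale. The 2-fold rule called 166.9 unchanged genes per run there, more than the 38 and 9 genes observed. The simulated noise thus appears too wide to give the number of false calls. Neither count measures how many genes changed.

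ER chaperones and folding enzymes were lower on both labelled arrays in 20 of 23 cases and higher on both in 1, and the list fell by camera (limma, adjusted p = 1.03e-08). With an estimated correlation camera did not call it (adjusted p = 0.594), but that run had 1 residual degree of freedom and could hardly call any list. The estimate for this list was 0.004, below the preset 0.01. It rests only on which hairpin array is higher for each gene, so it says little of how these genes vary together. The medians were -0.50 and -0.54 with the 2 hairpins. SDF2L1 differed by -0.91 and -1.59, PDIA4, a disulfide isomerase, by -0.78 and -0.95, CRELD2 by -0.87 and -0.84 and MANF by -0.74 and -0.91. HSPA5 differed by -0.50 and -0.47, HSP90B1 (GRP94) by -0.63 and -0.78 and the lectin chaperone CALR by -0.50 and -0.54. Limma called 0 members, also when adjusted over the list alone. ER chaperones were a theme of the study, so this list is not independent evidence of its direction. Against the 2D array the direction turned, with medians of 0.17 and 0.015 for the 2 hairpin arrays and 0.50 for the shGFP array, across sets of arrays whose control ratios differ (actin 5′ to 3′ ratio 0.184 in 2D and 0.436 with shGFP).

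Integrated stress response genes fell by camera (adjusted p = 0.00018, and adjusted p = 0.594 with an estimated correlation). Of 21 members 17 were lower on both labelled arrays, with medians of -0.47 and -0.39. The serine hydroxymethyltransferase SHMT2 was at -2.29 and -0.34 and the cystine carrier SLC7A11 at -1.78 and -0.39, so both were far lower with shTRIB1-1 than with shTRIB1-2. CHAC1, which degrades glutathione, was at -1.32 and -1.05, TRIB3 at -1.09 and -0.72 and DDIT3 at -0.47 and -0.92. Against the 2D array this list was higher too, with medians of 0.26 and 0.57, and shGFP stood 0.85 above 2D. Of 13 genes of ER-associated degradation and unfolded protein sensors, 8 were lower on both arrays and 3 higher, with a median of -0.16 and no call (adjusted p = 0.096, and adjusted p = 0.617 with an estimated correlation). HERPUD1 differed by -0.88 and -1.16 and SEL1L by -0.65 and -0.46. Against the 2D array the medians of this list turned to 0.30 and 0.39, and HERPUD1, at 10.02 in 2D, was higher on the labelled arrays, at 10.98 and 10.70.

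Cell cycle genes were lower on both labelled arrays. All 19 measured genes of G2 and M phase had this direction, with medians of -0.44 and -0.63, and the list fell by camera (adjusted p = 1.03e-08). With an estimated correlation the adjusted p = 0.594. KIF20A differed by -0.61 and -0.95, the survivin gene BIRC5 by -0.50 and -0.79, CENPF by -0.63 and -0.63 and MKI67 by -0.53 and -0.51. DNA replication genes fell as well (adjusted p = 9.3e-05, and adjusted p = 0.594 with an estimated correlation), 16 of 20 being lower on both arrays, with a median of -0.29. RFC4 differed by -0.65 and -0.64 and CDC45 by -0.35 and -0.85. Between the 2 adherent controls, shGFP and 2D, the median of the same 19 genes differed by -0.69 (shGFP minus 2D), more than between the hairpins and shGFP. Against the 2D array, the reference of the spheroid comparison, the medians of the labelled arrays were -1.04 and -1.33 for G2 and M phase and -1.22 and -1.33 for DNA replication.

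Interferon-stimulated genes rose on the labelled arrays by camera (adjusted p = 6.4e-05, and adjusted p = 0.594 with an estimated correlation). Of 14 members 11 were higher on both arrays, with medians of 0.36 and 0.64. ISG15, a ubiquitin-like modifier, differed by 0.95 and 0.75 and the RNA sensor IFIH1 by 0.95 and 0.72, whereas IFI44L was at 0.36 and 1.92 and IFI6 at 0.00 and 1.81. Antigen presentation genes rose (adjusted p = 0.0030, and adjusted p = 0.594 with an estimated correlation), 8 of 10 being higher on both arrays. Their medians were 0.50 and 0.25, with PSMB9 at 1.05 and 0.25 and TAPBP at 0.40 and 0.57. Against the 2D array the medians were 0.28 with shTRIB1-1 and -0.066 with shTRIB1-2, and 0.077 for the mean of the hairpins. Inflammatory genes had medians of 0.78 and 0.11, 5 of 11 higher on both arrays, and were not called (adjusted p = 0.063, and adjusted p = 0.668 with an estimated correlation). Against the 2D array their medians were 2.84 and 1.64. CCL20 differed by 2.53 and 0.66, IL6 by 1.58 and 0.90 and TNFAIP3 by 2.08 and 1.32.

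A further 4 lists passed camera with the preset correlation. Hypoxia response genes fell (adjusted p = 0.031, and adjusted p = 0.594 with an estimated correlation), 12 of 20 being lower on both labelled arrays, with the glucose carrier SLC2A1 at -0.74 and -0.74 but adrenomedullin (ADM) at 1.58 and 0.68. Their median was -0.24 against shGFP and 0.0029 against 2D. Cholesterol biosynthesis genes rose (adjusted p = 0.013, and adjusted p = 0.594 with an estimated correlation), 7 of 12 being higher on both arrays, with HMGCS1 at 1.14 and 0.35 and SC5D at 0.68 and 0.58. Their medians were 0.41 with shTRIB1-1 and 0.088 with shTRIB1-2, and the median for the mean of the hairpins, 0.23, was 0.015 without _s_at and _x_at probe sets and turned to -0.82 against 2D. Matrix and integrin genes rose (adjusted p = 0.030, and adjusted p = 0.594 with an estimated correlation), 10 of 19 being higher on both arrays. Their medians were 0.54 with shTRIB1-1 and 0.046 with shTRIB1-2, with the collagens COL4A2 at 1.96 and 0.76, COL5A1 at 1.66 and 0.68 and COL4A1 at 1.10 and 1.06, and the integrin ITGB4 at -1.07 and -0.60. Autophagy and lysosome genes rose (adjusted p = 0.011, and adjusted p = 0.693 with an estimated correlation), 11 of 16 being higher on both arrays. Their medians were 0.22 with shTRIB1-1 and 0.049 with shTRIB1-2, with the protease CTSB at 1.84 and 0.57, GABARAPL1 at 0.90 and 0.86, SQSTM1 at 0.66 and 0.27 and LAMP2 at 0.58 and 0.13. In total camera called 10 of 23 lists with the preset correlation and 0 with an estimated one. The 0 says little, because that run had 1 residual degree of freedom and could hardly call any list. The estimate was below the preset 0.01 for ER chaperones (0.004), integrated stress response (0.0095), interferon-stimulated (-0.0275) and hypoxia genes (-0.0421). These estimates rest only on which hairpin array is higher for each gene, so they cannot tell whether correlation between genes mattered. For the rest of the called lists it was above the preset, up to 0.44 for autophagy and lysosome genes. The fall to 1 residual degree of freedom raises the p-values, also where the estimate was below the preset.

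The other lists were not called on the labelled arrays. By camera with the preset correlation the adjusted p was 0.30 for heat shock proteins (median 0.05), 0.28 for epithelial junctions (0.13), 0.083 for mesenchymal genes (0.13), 0.518 for stem cell markers (0.10) and 0.518 for the TRIB1 family and its partners (0.06). It was 0.73 for prostate luminal genes (median -0.053), 0.056 for neuroendocrine genes (-0.26, 2 genes), 0.741 for blood and endothelial markers (-0.28, 2 genes), 0.318 for oxidative phosphorylation (-0.089), 0.73 for ribosomal proteins (-0.0093) and 0.523 for apoptosis regulators (-0.0044). For ribosomal proteins and apoptosis regulators camera gave the opposite sign to the median. Among single members, E-cadherin (CDH1) was at 1.37 and 0.53, fibronectin (FN1) at 1.48 and 0.86, S100A4 at -1.66 and -0.87, CD24 at 0.54 and 1.28, CD44 at 0.16 and -0.55 and VEGFA at -0.12 and 0.06. The pro-apoptotic gene BCL2L11 was at 0.88 and 0.51, and COX6C at 0.00 and -2.57.

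The labelled arrays were set against each other because 2 hairpins with 1 target should share the effects of its loss. Their differences from shGFP had Pearson's r = 0.296 and Spearman's rho = 0.337 across 10522 genes, which are not independent replicates. Unchanged arrays simulated against 1 shared control gave a mean r of 0.501, and a covariance of 0.116 against the observed 0.0475. The simulations gave a mean of 86.2 genes 2-fold higher and 87.3 2-fold lower on both arrays, above the observed 38 and 9. Independent lists of these sizes would share 2.81 and 1.60 genes. With shGFP as the control of shTRIB1-1 and 2D as that of shTRIB1-2, r was 0.110, and 0.242 with the controls exchanged. The simulated noise was drawn from the difference between the 2 hairpin arrays, which can also hold effects of 1 hairpin alone. The observed covariance and counts lay below the simulated ones, so that noise appears too wide for the shGFP array. The simulation therefore cannot tell whether the shared genes exceed what a shared control array can give. The r values without a shared control were above 0 but include the 2D array, whose control ratios differ. The 1 shGFP array could not be divided.

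The spheroid and hairpin differences were compared because the study examined both in the same cells. Across 10249 genes tested in both, they had Pearson's r = 0.332 and Spearman's rho = 0.297, with r = 0.212 for the array labelled shTRIB1-1 and 0.339 for the array labelled shTRIB1-2. These comparisons share no array. Of 445 genes 2-fold higher in the spheroid array and 36 on both labelled arrays, 16 were shared (1.56 for independent lists). Of 524 genes lower in the spheroid array and 8 on both labelled arrays, 4 were shared (0.409 for independent lists). The opposite pairs of directions held 2 genes (1.84) and 0 genes (0.347). Among the genes higher in both were ADAMTS1 (1.83 in the spheroid array), RGS4 (4.67), HDAC9 (1.37), COL1A1 (1.47) and HEG1 (1.29), of which HDAC9 and COL1A1 were near 0 and HEG1 below 2-fold over all probe sets, as given above for the hairpins. The genes lower in both were CALB1 (-3.80), TSNARE1 (-2.17), LRRC34 (-1.86) and SHISA2 (-1.04), of which CALB1 turned against 2D and TSNARE1 was near 0 over all probe sets, as given above for the hairpins. SKA1, a mitotic gene, came next, at -2.25 in the spheroid array and -0.87 and -1.07 with the hairpins. FSTL1 (-1.28) and OTULINL (-2.16) were lower in the spheroid array and higher on the labelled arrays. In the other direction HERPUD1 differed by 1.11 in the spheroid array, FSIP1 by 3.07 and SYBU by 1.34, against hairpin means of -1.02, -1.28 and -1.04. HERPUD1 was higher on the labelled arrays than in 2D, so its direction depends on the shGFP array, and FSIP1 was below a level of 6 in 2D and on both labelled arrays.

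Of the genes 2-fold higher in the spheroid array, 47.6% were higher on both labelled arrays and 11.9% were lower on both. Of the genes 2-fold lower, 11.1% were higher on both and 60.7% were lower. Over all 10249 genes these shares were 24.9% and 34.9%. Integrated stress response genes had opposite signs, with a median of 0.70 in the spheroid array and -0.44 on the labelled arrays. This depended on the reference, since the hairpin median was 0.41 against 2D and 0.0090 against the mean of shGFP and 2D, where the spheroid median was 0.17.

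**Figure D3:**
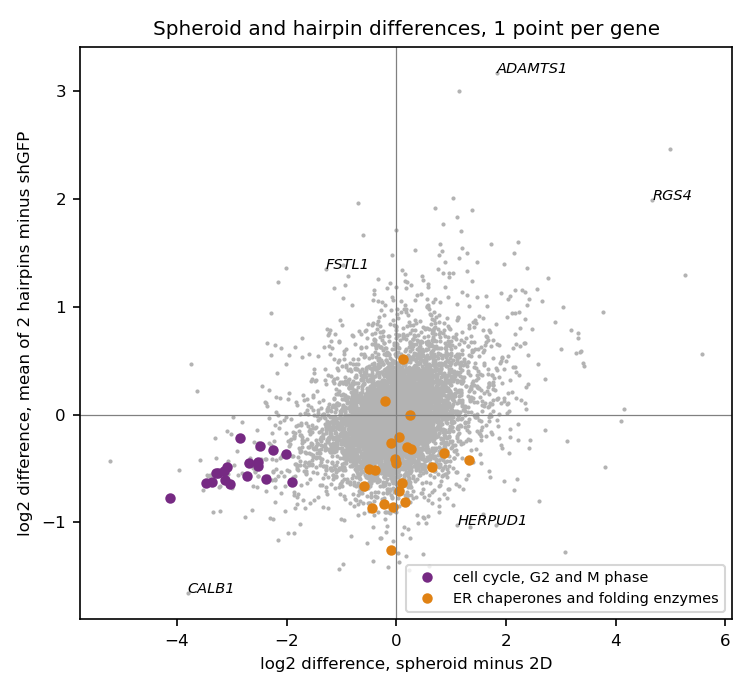
Log2 difference of spheroid minus 2D (horizontal axis) and mean log2 difference of the arrays labelled shTRIB1-1 and shTRIB1-2 minus shGFP (vertical axis), with 1 point for each of 10249 genes and colours for G2 and M phase genes and ER chaperones. The G2 and M phase genes lie in the lower left. Most ER chaperones lie below 0 on the vertical axis and on both sides of 0 on the horizontal axis. The medians over all members measured in a comparison, which include PLK1 and ERO1B (not plotted), were as follows. For spheroid minus 2D they were -2.78 for G2 and M phase and 0.02 for ER chaperones. For the hairpins they were -0.54 and -0.45.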

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

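The tests of exchanged labels, of a high shGFP level and of 5′ signal loss were chosen after the result was seen. The tests of compressed signals, of level shifts and of a difference between dishes were written before.

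Control probe sets outside the gene comparisons gave ratios of 3′ to 5′ signal that set the arrays without hairpins apart. For actin the ratio was 7.63 in the spheroid array and 5.45 in 2D, against 2.25 to 2.30 on the hairpin arrays. For the thr spike it was 8.83 in the 2D array and 10.9 in the spheroid array, against 3.72 to 4.61 on the hairpin arrays. Probe sets without a gene name, which no comparison used, also differed. In the spheroid array 143 of them were at least 2-fold higher than in 2D and 75 lower. On both arrays labelled shTRIB1, 6 were at least 2-fold higher than shGFP and 2 lower.

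TRIB1 was not clearly lower on the arrays labelled shTRIB1-1 and shTRIB1-2. For exchanged labels among the 3 hairpin arrays, the prediction was that 1 or 2 of them would lie 2-fold apart. Their TRIB1 levels spanned 0.20, with an SD of 0.334 for differences at that level. The prediction holds only if a hairpin lowered this messenger RNA, which no array shows, so the test cannot decide on exchanged labels. Full compression of bright signals is argued against by 2.10% of the 619 probe sets near that level differing 2-fold from shGFP with a hairpin. Partial compression stays open, because no share over all levels was set beside this one. A loss of TRIB1 protein alone, a loss before the RNA was taken, hairpins that did not act, or probes that miss the affected transcript stay open as untested.

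ER chaperones were lower on both arrays labelled shTRIB1. The list lay at percentile 0 of level-matched lists, so in the normalized values it stood apart from other genes at that level. Quantile normalization removes most shifts of all genes, so this test says little of a shift before it. A high level in the single shGFP array remained possible. The 2 hairpin arrays stood 0.17 and 0.015 above the 2D array rather than below it, in a test chosen after the result was seen. The 2D array differs in its control ratios and carries no hairpin, so it cannot show where an unaffected hairpin array would lie. A high shGFP level and an effect of the hairpins cannot be separated with 1 control array.

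Cell cycle genes were far lower in the spheroid array. Loss of 5′ signal as the whole cause is argued against by the G2 and M median of -2.78, below the lowest 5′ control difference of -0.76 by more than the SD over members (0.627). At percentile 0 among level-matched lists, the list stood apart from other genes at that level in the normalized values. That says little of a shift of all genes before normalization. A difference between dishes unrelated to spheroid growth cannot be told apart, since each condition had 1 array and the adherent shGFP array also stood at -0.70 from 2D over the list's 20 genes. An effect of spheroid growth, the difference that the design names, also stays open and was not tested.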

How the results depend on the processing

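The reference of 2D alone and the correlation without cell cycle lists were chosen after the result was seen, and the other alternatives before. No paired analysis was possible because the 2D, spheroid and shGFP groups hold 1 array each. Over all alternatives, 59 values of the comparisons moved little, 21 moved more and 0 turned a called direction (TRIB1, not called, changed sign). For list medians these numbers were 249, 98 and 9, and for named genes 317, 77 and 4. The cause was not tested unless stated. Arrays give no depth, and genes near the level filter are limited by signal over background.

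With the median over all probe sets, 20 genes were higher and 4 lower on both labelled arrays, and TRIB1 differed by 0.030. A level filter of 8, which tests fewer genes, left 23 higher on both arrays and 330 higher in the spheroid array. Against the mean of shGFP and 2D, 82 genes were higher and 32 lower on both arrays, TRIB1 differed by 0.33, and spheroid TRIB1 by -0.28. Against 2D alone 236 were higher and 238 lower. Each hairpin alone gave 141 to 210 higher and 86 to 196 lower, and r with the spheroid differences of 0.212 to 0.339, or 0.325 without the cell cycle lists. Limma over all 5 arrays, where the lone spheroid and 2D arrays are assumed to vary like the hairpins, called 0 higher and 0 lower in the spheroid array (1622 at an unadjusted p under 0.05). For the hairpins it called 0 in every fit (352 unadjusted over 5 arrays, 652 with shGFP and 2D as controls). Of the 2 other TRIB1 probe sets, 1 differed by 0.012 with the hairpins and 0.092 in the spheroid array, and the last by -0.076 and -0.091. Hairpin r without a shared control was 0.110, or 0.242 with the controls exchanged.

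Directions turned for the lists and genes below, where a list counts if camera called it (hairpins) or its median lay in the tails of the random lists (spheroid). The spheroid hypoxia median was -0.13 over all probe sets and -0.14 without _x_at and _s_at, where the epithelial one was 0.0082. Against the mean of shGFP and 2D, the hairpin medians were 0.0090 for the integrated stress response and -0.27 for cholesterol, and CALB1 was 0.0072. Against 2D alone they were 0.41, -0.82, 0.073 for ER chaperones and 0.0029 for hypoxia, CALB1 was 1.67, CHAC1 0.21 and SLC16A14 -0.048. Medians of lists not called changed sign too, among them the spheroid ones of mesenchymal genes (0.18 without _x_at and _s_at) and ER chaperones (-0.25 against the mean of 2D and shGFP), the hairpin one of ER-associated degradation (0.30 against 2D), and those of some lists near 0.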

Other observations

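The genes in this part were chosen after their values were seen, and no test was run on them.

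The arrays labelled shTRIB1-1 and shTRIB1-2 differed from each other in more genes (532 at least 2-fold) than either did from shGFP (396 and 223). These counts take genes at a level of at least 6 on either array of a pair, where the counts in the comparison with shGFP took any of its 3 arrays. The genes below were among those with the widest gaps between the 2 hairpins. IGFBP5, which binds insulin-like growth factors, was at -2.17 from shGFP with shTRIB1-1 and at 3.05 with shTRIB1-2, and the tetraspanin TSPAN8 at -0.81 and 3.05. The fatty acid carrier FABP4 was at -1.27 and 3.85, the muscarinic receptor CHRM3 at -2.55 and 1.07, and the pyruvate dehydrogenase kinase PDK4 at -1.05 and 2.01. In the other direction, TCIM was at 5.02 and 0.14, the interleukin receptor gene IL1RL1 at 2.49 and -0.19, and the phosphodiesterase PDE4B at 1.95 and -0.66. TCIM was at 2.95 with shGFP and 3.10 with shTRIB1-2. IGFBP5, FABP4, CHRM3, TSPAN8 and PDK4 were below a level of 6 with shTRIB1-1, and PDE4B with shTRIB1-2, so the sizes of these differences rest on a signal near background.

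Several of these genes were also higher in the spheroid array than in 2D. FABP4 differed there by 5.27, PDK4 by 3.40, IL1RL1 by 2.17, IGFBP5 by 2.12, TSPAN8 by 1.91 and PDE4B by 1.87, where IGFBP5, TSPAN8, PDK4 and PDE4B were below a level of 6 in 2D. The 2 adherent control arrays, shGFP and 2D, differed at least 2-fold in 444 genes, against 1087 between spheroid and 2D.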
